A study of Mus musculus with 6 samples.

How the data were processed

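RNA from the livers of 6 mice was sequenced, 3 labelled K and 3 labelled W at the start of their sample names. The series compares alkaline sphingomyelinase knockout mice with wildtype mice on a C57BL/6 background, and the letters were read as knockout (animals 82, 84 and 85) and wildtype (animals 81, 83 and 90). No other label gives the genotype. The tissue label says liver while the design text speaks of intestine, and marker genes of both tissues are given in the results for that reason. Per the labels' protocols, tissue was frozen, total RNA was taken up in Trizol, and libraries were made with the Illumina TruSeq RNA kit from 1 ug of RNA. Single-end reads of 50 nt were made on an Illumina HiSeq instrument. The labels do not say whether the libraries keep strand.

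Bowtie2 and the mouse build mm10 are named per the submitters' processing notes, with no version. The program that made the tables is not given in the sources used here, and neither is the handling of reads that map to several places. Genes with near-identical copies, among them Saa1 and Saa2, the Orm genes, Acot1 and Acot3, the Cyp4a genes, the metallothioneins and the globins, are therefore uncertain one by one.

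The authors deposited 1 table of all genes and 1 short list of differential genes. Both hold 1 expression value per group and not per mouse. The file headers do not name the unit of the deposited expression values; the layout is that of a Cuffdiff gene table, whose values are FPKM (fragments scaled for transcript length and for sequencing depth), and the values were treated as the authors' FPKM on that ground. The deposited log2 ratio is wildtype over knockout per the file headers, and it was turned round, so that every log2 ratio given here is knockout over wildtype. It differed from the log2 of the 2 deposited values by at most 1.29e-05. The authors' test statistic is a score that equals a standard normal z to within the rounding of its p-value (largest difference 2.63e-06). The authors' q-value is the Benjamini-Hochberg adjustment of that p-value over the 11515 tested genes (largest difference 1.99e-06).

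Of 23415 genes in the deposited table, 11515 were tested by the authors. Another 11734 carry the mark NOTEST, 157 LOWDATA, 7 FAIL and 2 HIDATA, which in a Cuffdiff table stand for too few alignments, a locus too shallow or complex, a failed calculation and too many fragments. The last 2 were Alb and Apoe, which are listed at 0 in both groups and so have no value here. No gene marked NOTEST exceeded 0.679 FPKM. Of the tested genes, 59 had a value of 0 in 1 group and no finite ratio, and they stayed out of medians and standard errors. The table holds 0 columns of samples from other series.

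Because no value per mouse was used here, no spread between replicates could be computed, and the test planned for values per library (limma on log2 values) was replaced by the fallback fixed beforehand. A gene is called when its q in the authors' deposited table is under 0.05, with no fold minimum. The standard error of a log2 ratio is the ratio divided by the deposited z. It is the error of the authors' model and not an observed spread. Its median over tested genes was 0.279 and its 5th percentile 0.223, so that small differences could not be called: the smallest absolute log2 ratio of a called gene was 0.78. No source here says whether each library came from a separate mouse, beyond the animal numbers in the names. Read totals are unknown. No depth and no counting interval can therefore be given.

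Before the data were examined, 23 functional gene lists and 13 marker lists of cell types and tissues were fixed, 36 in all. They hold 757 genes found in the table, some under older symbols: 21625 of the 23415 symbols occur as such in the RefSeq gene table of GRCm38.p6, and another 1633 are an older name of a single gene there. For each list the called members are counted per direction, and the count is repeated with q values adjusted over the list alone. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size, drawn from tested genes in 20 classes of mean FPKM. This percentile describes these values and is not a test over mice. It was computed for the 33 lists with at least 5 tested genes.

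The genes named were chosen by a rule fixed beforehand. It takes Enpp7 first, then the 10 called genes with the largest rise and the 10 with the largest fall, then up to 3 called members of each list with the smallest p, or where a list has none, its member with the smallest p, given as values only. Predicted genes, pseudogenes and microRNAs were left out of the naming but not of the counts. Every other gene named was chosen after its values were seen; these are the called members of lists beyond the 3 with the smallest p, the highest marker genes of liver and intestine, and the genes said so where they are named.

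Coordinates are those of the deposited table (mm10) with 1 added to each start, since the starts count from 0. With that addition, 49.5% of the 21511 symbols on the same chromosome have the start that RefSeq gives them on GRCm38.p6, and 49.2% have its end.

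The alternatives were a median centring of the log2 ratios, a quantile normalization between the 2 groups, a pseudocount of 1, 0.5 or 0.1, no filter, a mean FPKM of at least 1 or 5, thresholds of q under 0.01 or 0.1, and an absolute log2 ratio of at least 1. A scaling of both groups to the same sum of FPKM was added after the data were seen. Calls under another scaling used the shifted ratio over the same standard error. The calculation was tested on simulated data: ratios were drawn for 11391 tested genes with their standard errors, and 200 genes were changed. Of the genes changed by 1 on the log2 scale 53% were called, and of those changed by 2, 91%. Unchanged genes made up 7.69% of the calls. Of 200 simulated lists of 25 unchanged genes, 7.5% fell outside percentiles 2.5 to 97.5. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.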

Results

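Liver RNA of 3 Enpp7 knockout mice and 3 wildtype mice was compared. Enpp7 encodes alkaline sphingomyelinase, a membrane enzyme of the intestine that splits sphingomyelin. The question was which liver transcripts differ in its absence. Expression is given as the authors' FPKM value per group. Ratios are log2 of knockout over wildtype, followed by the standard error that the authors' z statistic implies, and nothing here measures the spread between mice. Pairs of values written with "against" give knockout first, and a gene that went from one value to another goes from wildtype to knockout. A gene is said to have risen or fallen when its q in the authors' deposited table is under 0.05. Read depth per library is unknown.

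Enpp7 itself (chromosome 11, 118988188 to 118992841, mm10) stood near the floor in both groups. Its value was 0.141 FPKM in the knockout group and 0.0541 FPKM in the wildtype group, and it was not tested in the authors' deposited table. The log2 ratio of 1.38 ± 1.67 (SE) is smaller than its error. At this level the gene does not check the genotype labels. Among its relatives, 5 of the 7 ENPP genes listed were tested and 0 changed, with 1 at an unadjusted p under 0.05. That gene was Enpp3, a nucleotide pyrophosphatase, at 22.4 against 13.5 FPKM (log2 ratio 0.73 ± 0.23, q = 0.102 in the authors' deposited table), and it passed when q was adjusted over the list alone.

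The livers carried the transcripts of hepatocytes in both groups. The median of 13 hepatocyte markers was 1031 FPKM in the knockout group and 1219 FPKM in the wildtype group, led by Apoa1, the main protein of high-density lipoprotein, at 16007 and 11662 FPKM. The median of 25 intestinal epithelium markers was 0.738 and 0.280 FPKM. The highest of these were Tff3, a trefoil peptide, at 48.8 FPKM in the knockout group and Fabp2, a fatty acid binding protein, at 54.7 FPKM in the wildtype group. None of 13 tested hepatocyte markers changed, and 0 had an unadjusted p under 0.05. Tat, tyrosine aminotransferase, had the smallest p of them, at 769 against 1219 FPKM (log2 ratio -0.66 ± 0.36).

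Transcripts of the acute phase response and of neutrophils made up most of the largest rises in the knockout livers. Saa2 and Saa1, serum amyloid A proteins that the liver secretes in inflammation, stood at 17481 and 14989 FPKM in the knockout group against 86.2 and 169 FPKM in the wildtype group, which is 203-fold and 88.9-fold. Together they held 5.02% of the listed FPKM in the knockout group and 0.0451% in the wildtype group, where the listed FPKM leave out Alb and Apoe, which have no value here. Lcn2, an iron-scavenging protein of hepatocytes and neutrophils, rose 84.1-fold and Orm2, an alpha-1-acid glycoprotein, 68.2-fold. The largest falls were smaller in size and included enzymes of fatty acid metabolism. Cml5 (now Nat8f5), a gene of the N-acetyltransferase 8 family, fell by 2.79 on the log2 scale and Acot3, a peroxisomal acyl-CoA thioesterase, by 2.55.

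Of 11515 tested genes, 124 passed q under 0.05 in the authors' deposited table, 66 of them higher and 58 lower in the knockout group. At an unadjusted p under 0.05 there were 609, or 5.29% of those tested, where 576 are expected by chance. The median log2 ratio of the tested genes was -0.0012. The listed FPKM values, without Alb and Apoe, summed to 646306 in the knockout group and 564749 in the wildtype group. Scaling both groups to the same sum, an alternative added after the data were seen, moved the median to -0.20 and the calls to 49 higher and 140 lower. All directions below refer to the values as deposited.

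**Figure D1:**
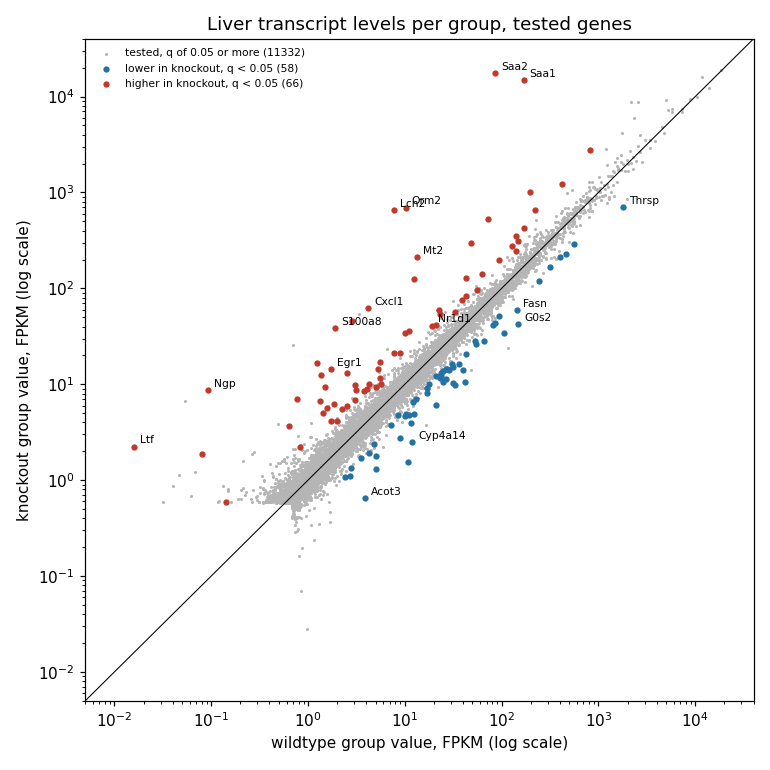
Value of each tested gene with a finite ratio in the wildtype group (horizontal axis, FPKM, log scale) against the knockout group (vertical axis, FPKM, log scale), with the line of equal values. The 66 genes higher in knockout at q under 0.05 are red, with Saa2 and Saa1 at the top, the 58 lower genes are blue, and 11332 other genes are grey.

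The 10 named genes with the largest rise were Saa2 (log2 ratio 7.66 ± 0.69), Ltf (7.15 ± 1.80), Ngp (6.55 ± 1.27), Saa1 (6.47 ± 0.65), Lcn2 (6.39 ± 0.35), Orm2 (6.09 ± 0.34), Chi3l3 (4.53 ± 1.30), S100a8 (4.34 ± 0.71), S100a9 (4.01 ± 0.50) and Mt2 (3.99 ± 0.32). Ltf, Ngp, S100a8 and S100a9 are granule or cytosolic proteins of neutrophils, Chi3l3 (now Chil3) is a chitinase-like protein of myeloid cells, and Mt2 is a metallothionein. Saa1 lies on chromosome 7 at 46740499 to 46742980 and Saa2 beside it at 46751833 to 46754314. Lcn2 lies on chromosome 2 at 32384637 to 32387739 and Orm2 on chromosome 4 at 63362449 to 63365877. The q of Saa1, Saa2, Lcn2, Orm2 and Mt2 is printed as 0 in the authors' deposited table. Ltf and Chi3l3 were at 0.0158 and 0.0808 FPKM in the wildtype group, so their ratios rest on values near the floor. Chi3l3 (q = 0.0467 in the authors' deposited table) no longer passed after quantile normalization (q = 0.400) or scaling to the same sum (q = 0.0515).

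The 10 largest falls were those of Cml5 (-2.79 ± 0.45), Acot3 (-2.55 ± 0.42), Cyp4a14 (-2.27 ± 0.31), Mfsd2a (-1.97 ± 0.24), Ppp1r3g (-1.95 ± 0.37), G0s2 (-1.78 ± 0.23), Cyp4a10 (-1.78 ± 0.27), Rgs16 (-1.73 ± 0.25), Acot1 (-1.70 ± 0.33) and Tsku (-1.60 ± 0.27). Cyp4a14 and Cyp4a10 are fatty acid omega-hydroxylases, Mfsd2a carries lysophosphatidylcholine into cells, and Ppp1r3g directs protein phosphatase 1 to glycogen. G0s2 inhibits the triglyceride lipase ATGL, Rgs16 is a regulator of G protein signalling, and Tsku is a secreted protein of the liver. G0s2 was the most abundant of these in wildtype livers, at 148 FPKM against 42.9 FPKM in the knockout group. Cml5 lies on chromosome 6 at 85817218 to 85820972, and G0s2 on chromosome 1 at 193272160 to 193273188.

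Of the 31 members of the acute phase list, all tested, 14 rose, 0 fell and 17 did not pass, and 29 of the 31 ratios were above 0. Adjusted over the list alone, 21 were higher and 1 lower. The median log2 ratio was 1.35, above all 10000 random lists (percentile 100). Besides the 5 members already named, Orm3, Saa3, Mt1, Apcs, Socs3, Orm1, Itih3, Lbp and Serpina3n rose, among them Apcs, the serum amyloid P component, from 47.7 to 296 FPKM and Socs3, a feedback inhibitor of cytokine signalling, from 2.55 to 13.0 FPKM. The whole list held 12.8% of the listed FPKM in the knockout group and 3.86% in the wildtype group.

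Of 19 tested members of the list of chemokines and cytokines, 4 rose and 0 fell: Cxcl1, a neutrophil attractant, from 4.21 to 62.9 FPKM (log2 ratio 3.90 ± 0.37), Cxcl14 from 1.33 to 6.77 FPKM (2.35 ± 0.38), Icam1, a leukocyte adhesion receptor, from 5.53 to 11.6 FPKM (1.07 ± 0.26), and Ccl2, a monocyte attractant, from 0.631 to 3.68 FPKM. The same 4 in number passed when adjusted over the list alone. The list median of 0.16 lay at percentile 98.2 and turned to -0.04 when both groups were scaled to the same sum.

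Interferon response and antigen presentation genes held no call. Of 36 tested interferon genes 0 changed, 3 had an unadjusted p under 0.05, all higher, and 2 were higher when adjusted over the list alone. Their median of 0.23 lay at percentile 100, and Irf1, an interferon-induced transcription factor, was at 22.3 against 11.4 FPKM (0.96 ± 0.30, q = 0.0990 in the authors' deposited table). All 19 tested antigen presentation genes had ratios above 0, with a median of 0.26 at percentile 99.97. None of them passed, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. H2-Aa, an MHC class II chain, had the smallest p, at 41.2 against 29.7 FPKM.

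Marker genes of myeloid cells stood higher in the knockout livers. Of 12 tested neutrophil and monocyte markers 5 rose (S100a8, S100a9, Ngp, Ltf and Lcn2) and 0 fell, 9 were higher when adjusted over the list alone, and the median was 4.18 at percentile 100. With a pseudocount of 1 or 0.5 that median was 1.68 or 2.27. Lcn2 is also on the acute phase list, and hepatocytes make it too. S100a8 rose from 1.89 to 38.4 FPKM and S100a9 from 2.86 to 46.0 FPKM. Of 15 Kupffer cell and macrophage markers, Marco, a scavenger receptor, rose from 2.52 to 5.96 FPKM and C1qa, a complement component, from 55.7 to 96.4 FPKM. Every one of the 15 ratios was above 0, with a median of 0.59 at percentile 100, and 9 were higher when adjusted over the list alone. Marco passed no longer with both groups scaled to the same sum (q = 0.0717), and C1qa (q = 0.0484 in the authors' deposited table) passed neither there (q = 0.253) nor after quantile normalization (q = 0.0580).

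Of 11 cholangiocyte markers Spp1, osteopontin, rose from 62.6 to 142 FPKM (1.18 ± 0.25), alone also when adjusted over the list alone. The list median was 0.30 at percentile 99.1. Endothelial and stellate cell markers lay on the other side. The 15 sinusoidal endothelium markers had a median of -0.18 (percentile 0.66) and the 15 stellate cell and fibroblast markers -0.23 (percentile 0.21), with 13 ratios below 0 in each list. No member of either passed, over all genes or adjusted over the list alone, and 1 and 3 had an unadjusted p under 0.05, all lower. Ehd3 was at 11.0 against 16.0 FPKM and Reln at 2.13 against 3.43 FPKM. With both groups scaled to the same sum Reln passed as lower (q = 0.0174).

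Lymphocyte, red cell and other tissue markers held no call. Red blood cell markers had a median of 0.61 over 8 tested genes (percentile 100), 3 of them higher when adjusted over the list alone and 3 at an unadjusted p under 0.05. Hbb-bt, a beta globin, was at 35.0 against 17.5 FPKM (1.00 ± 0.30, q = 0.0653 in the authors' deposited table). The 13 tested intestinal epithelium markers had a median of 0.73 (percentile 100), which was 0.34 with a pseudocount of 1 and 0.43 with 0.5. Of them 5 had an unadjusted p under 0.05 and 1 was higher when adjusted over the list alone, Tff3 at 48.8 against 23.9 FPKM (q = 0.0775 in the authors' deposited table). The 5 tested T and NK cell markers had a median of 0.14 (percentile 68.4), the 5 pancreas markers -0.04 (percentile 33.9) and the 7 adipose markers -0.17 (percentile 6.50). Of these 3 lists 0 members passed adjusted over the list alone, and 0, 0 and 1 had an unadjusted p under 0.05. Il2rb was at 0.861 against 0.689 FPKM, Prss2 at 0.0283 against 0.988 FPKM, and Adrb3 at 3.36 against 1.97 FPKM. B cell and muscle lists had 2 tested members each and none at an unadjusted p under 0.05, with Cd79b at 0.931 against 1.19 FPKM and Myh11 at 0.507 against 0.696 FPKM.

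Of 23 tested genes of fatty acid synthesis 7 fell, 1 rose and 15 did not pass, 20 ratios were below 0, and the median of -0.46 lay at percentile 0. Adjusted over the list alone, 11 were lower and 1 higher. Elovl6, which elongates long-chain fatty acids, fell from 39.6 to 14.0 FPKM (-1.50 ± 0.23), Thrsp, a lipogenic nuclear protein, from 1778 to 711 FPKM (-1.32 ± 0.28), and Fasn, fatty acid synthase, from 144 to 59.1 FPKM (-1.28 ± 0.27). Fasn lies on chromosome 11 at 120805958 to 120824547, within 5 Mb of Enpp7. The other members that fell were Pklr, Me1, Acacb and Acaca. Elovl3, an elongase of very long chains, rose from 32.8 to 57.3 FPKM (0.80 ± 0.23, q = 0.0484 in the authors' deposited table). It no longer passed after quantile normalization (q = 0.0580) or scaling to the same sum (q = 0.247).

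Targets of PPAR-alpha, the nuclear receptor that induces fatty acid oxidation, also lay mostly lower. Of 33 tested members 5 fell, 0 rose and 28 did not pass, 29 ratios were below 0, and the median of -0.22 lay at percentile 0. Adjusted over the list alone, 7 were lower. Those that fell were Cyp4a14 (11.9 to 2.48 FPKM), Cyp4a10 (20.8 to 6.04 FPKM), Acot3 (3.84 to 0.657 FPKM), Acot1 (9.03 to 2.77 FPKM) and Acaa1b (562 to 292 FPKM), a peroxisomal thiolase. The mitochondrial oxidation genes Cpt1a, Acadm and Hadha, chosen after their values were seen, did not pass, at ratios of -0.40, -0.18 and -0.09.

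Of 40 tested genes of drug metabolism 6 fell, 0 rose and 34 did not pass, 37 ratios were below 0, and the median of -0.38 lay at percentile 0. Adjusted over the list alone, 10 were lower. Gstt3, a glutathione transferase, fell from 31.2 to 15.1 FPKM (-1.05 ± 0.24), Cyp2a5, a coumarin hydroxylase, from 462 to 229 FPKM (-1.01 ± 0.25) and Gstm3 from 81.4 to 41.2 FPKM (-0.98 ± 0.25), and Cyp2c55, Ces1d and Por fell too. Gstm3 was the only member of the NRF2 list that passed, among 23 tested. That list's median was -0.03 (percentile 19.9), with 2 lower when adjusted over the list alone.

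In glucose metabolism Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, fell from 65.3 to 28.5 FPKM (-1.20 ± 0.23). It was 1 of 20 tested members, of which 19 had ratios below 0. The median of -0.30 lay at percentile 0, and 5 were lower when adjusted over the list alone. In the bile acid list Slco1a4, an organic anion transporter, fell from 24.8 to 10.5 FPKM (-1.24 ± 0.24) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 28.6 to 14.0 FPKM (-1.02 ± 0.24). The other 24 tested members did not pass, the same count of 2 was lower when adjusted over the list alone, and the median of -0.01 lay at percentile 29.2.

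**Figure D2:**
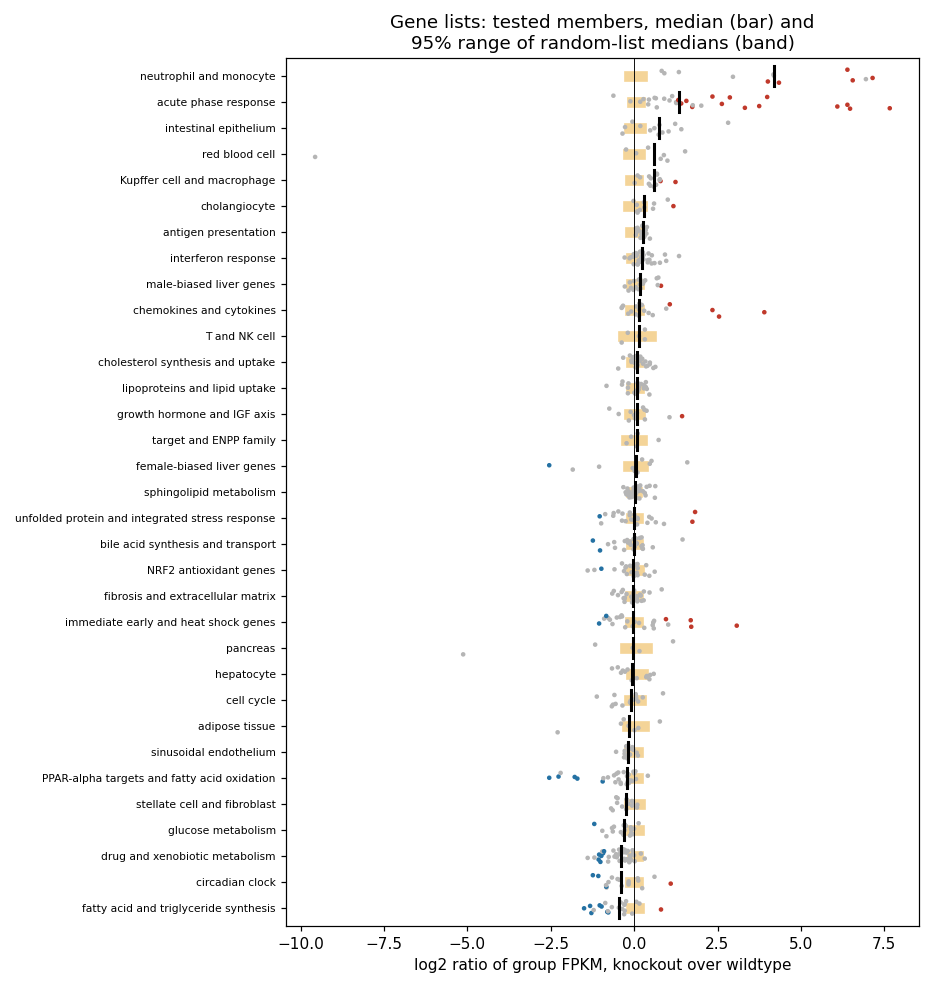
Log2 ratio of group FPKM, knockout over wildtype (horizontal axis), for the tested members of each list with at least 5 of them (1 row per list, points red if higher and blue if lower at q under 0.05). Black bars are list medians and bands hold 95% of the medians of random lists; the neutrophil and acute phase medians of 4.18 and 1.35 lie far to the right of their bands, and fatty acid synthesis at -0.46 lies left of its band.

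Sphingolipid, cholesterol and lipoprotein genes held no call. Sphingolipid metabolism had 39 tested members, a median of 0.04 (percentile 79.8) and 1 gene at an unadjusted p under 0.05. This was Smpd3, a neutral sphingomyelinase, at 2.34 against 1.52 FPKM (0.62 ± 0.31). Cholesterol synthesis and uptake had 25 tested members, a median of 0.10 (percentile 96.4) and 4 genes at an unadjusted p under 0.05, 3 of them higher. Mvk, mevalonate kinase, was at 33.6 against 21.6 FPKM (0.64 ± 0.24). The 22 lipoprotein and lipid uptake genes had a median of 0.10 (percentile 84.8) and 0 at an unadjusted p under 0.05, with Abca1, a cholesterol exporter, at 14.8 against 19.0 FPKM. In these 3 lists 0 members passed when adjusted over the list alone. With standard errors above 0.2, changes under about 0.78 on the log2 scale could not have been called. Larger ones could be missed as well, since 53% of the genes changed by 1 in the simulated data were called.

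Immediate early genes moved both ways. Egr1, a zinc finger factor, rose from 1.71 to 14.5 FPKM (3.08 ± 0.32) and Junb, an AP-1 subunit, from 11.1 to 36.3 FPKM (1.71 ± 0.25). Myc and Gadd45g rose as well, while Dusp1, a MAP kinase phosphatase, fell from 42.4 to 20.5 FPKM (-1.05 ± 0.24) and Hsph1, a heat shock protein, also fell. The other 19 of 25 tested members did not pass. Adjusted over the list alone 4 were higher and 3 lower, and the median was -0.04 (percentile 25.5). In the stress response list Derl3 rose from 1.59 to 5.64 FPKM (1.83 ± 0.42) and Chac1, a glutathione-degrading enzyme, from 1.85 to 6.21 FPKM (1.75 ± 0.37), while Creld2 fell from 54.2 to 26.5 FPKM (-1.03 ± 0.24). The remaining 22 did not pass, the median was 0.00 (-0.0026, percentile 39.2), and 3 were higher and 4 lower when adjusted over the list alone.

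Of 18 tested clock genes 3 fell, 1 rose and 14 did not pass, with a median of -0.41 at percentile 0. Adjusted over the list alone, 7 were lower and 1 higher. Usp2, a deubiquitinase with daily cycling, fell from 26.7 to 11.3 FPKM (-1.24 ± 0.24) and Ciart, listed under its older symbol Gm129, from 17.1 to 8.12 FPKM (-1.07 ± 0.28), and Per2 fell too. Nr1d1, the repressor REV-ERB alpha, rose from 19.2 to 41.0 FPKM (1.10 ± 0.23). The hour of harvest is not given in the sources used here.

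On the growth hormone list Cish, a feedback inhibitor of cytokine receptors, rose from 7.77 to 21.0 FPKM (1.44 ± 0.28) and 12 members did not pass. Its median was 0.09 (percentile 80.5), with 2 higher and 1 lower when adjusted over the list alone. Male-biased liver genes had Elovl3 as their only call among 20, with 2 higher when adjusted over the list alone. Their median of 0.18 (percentile 99.0) turned to -0.02 when both groups were scaled to the same sum. Female-biased genes had Acot3 as their only call among 10, a median of 0.06 (percentile 62.1), and 3 lower and 1 higher when adjusted over the list alone. Of the 4 tested sex chromosome genes 0 changed and 0 had an unadjusted p under 0.05, with the Y-linked Kdm5d at 2.09 against 1.80 FPKM. Cell cycle genes (17 tested, median -0.10, percentile 6.78) and matrix genes (26 tested, median -0.03, percentile 33.5) held no call, with 2 and 3 members at an unadjusted p under 0.05. Rrm2, a ribonucleotide reductase subunit, was at 2.07 against 4.51 FPKM (q = 0.0757 in the authors' deposited table), and 1 cell cycle gene was lower when adjusted over the list alone. Timp3, an inhibitor of matrix proteases, was at 4.93 against 7.78 FPKM, and 0 matrix genes passed adjusted over the list alone. With both groups scaled to the same sum, Rrm2 (q = 0.00987) and Timp3 (q = 0.0424) passed as lower.

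Over the 33 lists with at least 5 tested genes, 10 medians lay in the top 2.5% of the random medians and 7 in the bottom 2.5%. By chance 1.65 in all are expected if the genes within a list move independently of one another. Genes of a list that share regulators do not, so more medians than that can lie outside by chance. Several lists also share members or regulators, so the lists are not independent of one another.

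**Figure D3:**
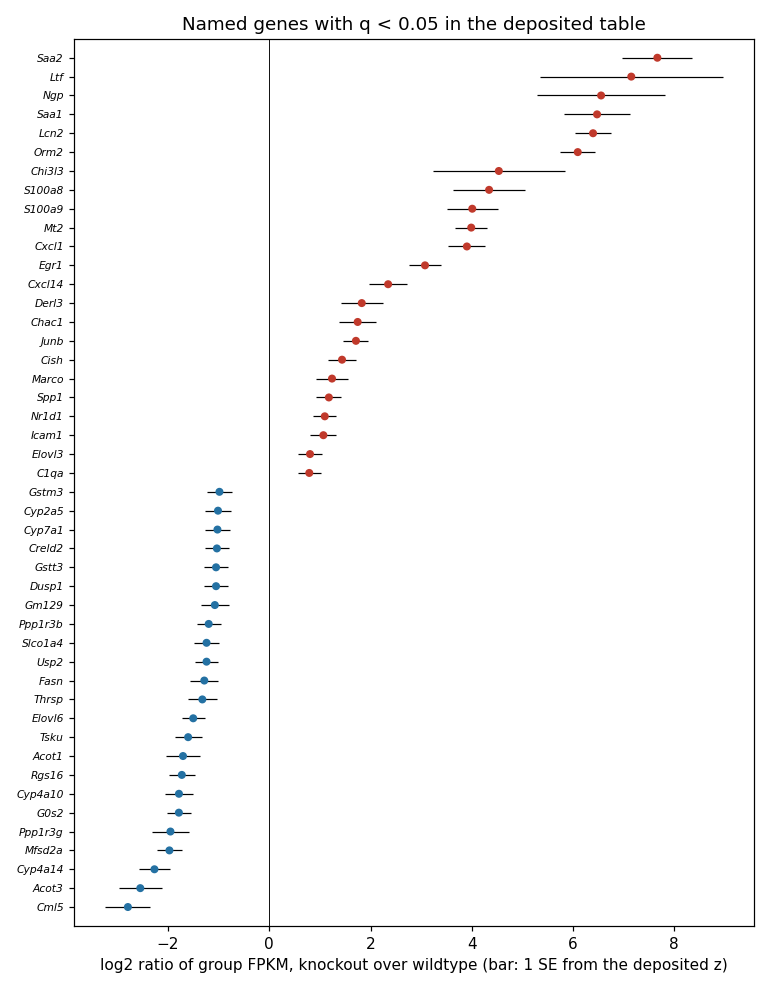
Log2 ratio of group FPKM, knockout over wildtype (horizontal axis), for the named genes with q under 0.05 (vertical axis), with bars of 1 SE from the deposited z. The ratios run from -2.79 for Cml5 to 7.66 for Saa2, and the longest bars belong to Ltf, Chi3l3 and Ngp, which were near the floor in wildtype livers.

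The authors' short list held 95 genes, 58 higher and 37 lower in the knockout group. Saa2 headed the rises there and Cml5 the falls, as in the table of all genes. Each of the 95 had q under 0.05 in the authors' deposited table, with the same values. The 29 called genes left off the short list, 8 higher and 21 lower, all had absolute log2 ratios of 0.99 or less, among them Elovl3, C1qa, Gstm3, Acaca and Acacb. The smallest absolute ratio on the short list was 1.01.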

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

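The scaling to the same sum of FPKM was chosen after the data were seen; the other alternatives were fixed before the data were examined. The count of 124 called genes stayed between 104 and 126 under median centring, quantile normalization, no filter and a mean FPKM of at least 1 or 5, and was 164 at q under 0.1; Saa1, Saa2, Lcn2, Fasn and Cyp4a14 kept their calls under the 3 scalings. With both groups scaled to the same sum it was 189, of which 140 were lower and 107 were among the 124, since every ratio then drops by 0.19. At q under 0.01 there were 79, of which 32 were lower, and with an absolute log2 ratio of at least 1 there were 95, of which 37 were lower; these are subsets of the 124 by construction. Named genes kept their side of the threshold under the scalings apart from Chi3l3, Elovl3, Marco and C1qa, which lost it in 7 cases, and Rrm2, Timp3 and Reln, which gained it, each with the q given in the results. A pseudocount shrank the ratios of low genes such as Ltf and Ngp beyond their standard error in 19 cases and reversed no called gene. The log2 ratio of Enpp7 ran from 0.11 with a pseudocount of 1 to 1.38, within its standard error.

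The lists with medians in the bottom 2.5% numbered 11 with no filter, against 7, and 7 or 8 otherwise; the cause was not tested. Medians that entered it were those of hepatocyte markers after quantile normalization (-0.29), immediate early genes with no filter (-0.12) and at a mean FPKM of at least 5 (-0.16), pancreas markers with no filter (-1.11), B cell markers (-0.35) and muscle markers (-0.45) with no filter, both too few to place before, and stress response genes at a mean FPKM of at least 5 (-0.11), where the stellate cell markers (-0.23) left it, at percentile 2.67. With no filter the cholangiocyte median was 0.53 and the clock median -0.27, both in the same tail as before. Under the alternatives fixed beforehand, the medians that changed sign lay in neither tail before or after. These were female-biased (-0.05) and lipoprotein genes (-0.03) after quantile normalization, and T and NK cell markers (-0.10) with no filter. Female-biased genes (-0.04) at a mean FPKM of at least 1 and matrix genes (0.08) at a mean FPKM of at least 5 changed sign too. Under scaling to the same sum 9 list medians changed sign from above to below 0, by the shift of all genes. Those of the chemokine list (-0.037) and the male-biased list (-0.0194) stayed in the top 2.5% of random lists; the other 7, in neither tail before or after, were T and NK cell markers (-0.05), cholesterol (-0.09), lipoprotein (-0.10), growth hormone (-0.11), ENPP (-0.11), female-biased (-0.14) and sphingolipid genes (-0.16). By the mean of log2 values the hepatocyte markers stood at 1578 FPKM in the knockout group and 1586 FPKM in the wildtype group, where the medians were 1031 and 1219 FPKM. The intestinal markers stood at 0.861 and 0.499 FPKM in the same order, where the medians were 0.738 and 0.280 FPKM. The cause of these differences was not tested. All 95 genes of the authors' short list passed at q under 0.1 and at an unadjusted p under 0.05, which follows by construction from their q under 0.05. Not run, as the tables used here hold 1 value per group, were the count-based tests, the limma settings, camera and fry, leaving out single libraries, and regroupings of the 6 libraries. No paired analysis was possible because the groups share no animal numbers and no values per library were used. Read depth is unknown, so genes near the floor, Enpp7 among them, cannot be judged.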

Other observations

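The values of this paragraph and the next were chosen after they were seen. Of the 124 called genes, 63 were on no list, 32 higher and 31 lower. Among those higher, Tnfaip3, a feedback inhibitor of NF-kappaB, rose from 0.766 to 7.02 FPKM (log2 ratio 3.19 ± 0.37), Nfkbiz from 1.41 to 5.07 FPKM (1.84 ± 0.37) and Tlr2, a receptor for bacterial lipopeptides, from 0.829 to 2.22 FPKM (1.42 ± 0.40). Fgl1 rose from 199 to 1004 FPKM and Lrg1 from 424 to 1237 FPKM. Foxq1, a forkhead factor, rose to 33.9 FPKM (1.76 ± 0.26) and the tight junction protein Cldn1 to 14.4 FPKM (1.43 ± 0.25). Enho, which encodes adropin, rose from 22.9 to 53.7 FPKM. Among those lower, Ccrn4l (now Noct), a deadenylase with daily cycling, fell from 31.2 to 10.4 FPKM, the lipase Lipg from 12.4 to 4.94 FPKM, the retinoic acid hydroxylase Cyp26a1 from 11.5 to 3.92 FPKM, the kinase Sik1 from 11.2 to 4.79 FPKM and the transferrin receptor Tfrc from 7.29 to 3.79 FPKM.

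Several abundant genes differed by more than many called ones and were not called. Their ratios carry large errors: the implied standard error had a median of 0.517 over the 23 genes of at least 3000 FPKM, against quartiles of 0.223 and 0.246 at 30 to 100 FPKM. Hp, haptoglobin, stood at 8785 against 2177 FPKM (2.01 ± 0.73, q = 0.268 in the authors' deposited table), Hpx, hemopexin, at 8746 against 2588 FPKM (1.76 ± 0.74), and the fibrinogen chain genes Fga, Fgb and Fgg had log2 ratios of 1.26, 1.35 and 1.26. Scd1, a desaturase, stood at 847 against 1964 FPKM (-1.21 ± 0.45, q = 0.299 in the authors' deposited table). Of 10 genes with a mean above 1000 FPKM and an absolute log2 ratio above 1, 6 were not called. Within 5 Mb of Enpp7, 2 of 148 tested genes were called, Fasn and Socs3 (two-sided Fisher's exact p against the other tested genes = 0.675). Of 77 tested ribosomal protein genes 0 were called and 71 had ratios above 0, with a median of 0.15, which turned to -0.04 with both groups scaled to the same sum. The listed Y-linked genes Ddx3y, at 8.78 and 9.52 FPKM, and Eif2s3y, at 20.7 and 22.7 FPKM, were expressed in the knockout and wildtype groups. Xist, on the same list, was at 0.00337 and 0.0491 FPKM in that order and was not tested by the authors.

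The tests in the following 3 paragraphs were chosen after the values were seen, apart from those of the time of day, the red cell median, the centring and the errors of acute phase genes relative to genes of like level. The acute phase genes were higher in the knockout group. For blood in the tissue as the source, the red cell markers of at least 1 FPKM had a median log2 ratio of 0.80. That is past the 0.5 first set as what blood would give, so more blood in the knockout livers stays open. Their summed rise of 99.7 FPKM was 0.0031 of the 32216 FPKM by which Saa1 and Saa2 rose. This share was added after the levels were seen and uses genes picked for their large rise. By itself it decides nothing for the other acute phase genes. Over the whole acute phase list, fixed beforehand, the median level was 636 against 174 FPKM. Globin transcripts dominate blood RNA, yet the summed red cell rise was smaller than the gap between these medians. That argues against blood as the source for the list as a whole and leaves single members undecided. No spread between mice is known for these values. For neutrophil transcripts, S100a8 and S100a9, among the most abundant in that cell, rose by 0.00247 of the rise of Saa1 and Saa2. That share likewise leaves single acute phase genes undecided. Their summed rise of 79.6 FPKM was also smaller than the gap between the list medians. For the list as a whole this argues against neutrophils as the source. Variants carried along with the targeted locus and acting on the genes beside them would place the genes near it, and 1 of the 14 called acute phase genes (7.14%), Socs3, lies within 5 Mb. What also stays open is a hypothesis of an inflammatory response of the liver's own cells, hepatocytes or others. Which of the liver's own cells carry the rise was not tested. Such a response may follow from the genotype, from a carried variant that acts on distant genes (not tested), or from an infection, injury or handling that differed between the groups. No value here separates these.

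Lipogenic genes and PPAR-alpha targets were lower in the knockout group. A share of the reads taken up by acute phase transcripts would lower all genes alike, by 0.14 on the log2 scale (-0.141). Both list medians lay below those of all random lists (percentile 0), where a shift of all genes would not place them. Each of the 12 called falls, of at least 0.78, exceeded that shift by 2.86 standard errors or more. That excess decides nothing, since the 12 were picked for passing the threshold, which already sets them that far out. Its bound was also set after an earlier one was missed. With the shift added back 9 of the 12 calls stayed, short of a bound set earlier. Those of Acaa1b, Acacb and Acaca ended (-0.80 ± 0.26, -0.67 ± 0.22 and -0.63 ± 0.22, before -0.94, -0.81 and -0.78) as smaller ratios over the same errors. That count does not measure whether the shift is as large as the falls. The planned centring (100% of the 12 kept) decides nothing, since the deposited ratios already have a median near 0. That median of all tested genes (-0.0012) shows no shift of -0.141 in the deposited ratios, where the list medians were -0.46 and -0.22. Together with the percentiles, this argues against a share of the reads as the cause for both lists as wholes. A longer fast in the knockout mice would lower lipogenic genes and raise PPAR-alpha targets, yet 5 of the latter fell and 0 rose (list median -0.22), so a fast does not account for both lists, while for the lipogenic genes alone (median -0.46) it cannot be told apart from the genotype. Another time of day at harvest cannot be told apart from the genotype: the Per and Dbp arm of the clock had a median of -0.44 over 11 genes and the opposing arm 0.11 over the 3 genes tested, neither beyond the 0.5 set for an opposite shift nor both within 0.25 of the other genes. The Per and Dbp arm did not move as one, since its member Nr1d1 rose (1.10 ± 0.23) while Usp2, Ciart and Per2 fell. A link between the inflammatory rise and the metabolic fall is a further candidate explanation and was not tested, as it needs values per mouse.

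The implied standard errors of genes of equal level were nearly equal. Among 1189 genes of 30 to 100 FPKM the quartiles were 0.223 and 0.246, a ratio of 1.10, where errors estimated from each gene's own 6 libraries would give at least 1.67. The test set first took the 12 called acute phase genes of at least 10 FPKM. Their errors were 1.31 times those of genes of like level at the median (median absolute deviation 0.114), 1.02 times at the lowest and 2.497 times at the highest. That median was past the bound set for a shared error. The deviation is the spread of these genes and does not measure the error of their median. The relative errors do not speak against a shared error, since the level of a gene was its mean over both groups. These genes stood lower in wildtype livers than that mean, so an error set by level alone could differ too. The ratio of 1.10 argues against errors estimated from each gene's own libraries alone, for the 1189 genes. An error model shared between genes cannot be told apart from one with a further part specific to the gene. An acute phase rise carried by a single knockout library may stand behind the pooled values: it would give a standard error near 1.44 if the error were estimated per gene, above the 0.693 of Saa2, the highest of the 12, but a shared error would hide it, so the number of mice that carry the rise cannot be told.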
